A study of Triticum aestivum with 12 samples.

How the data were processed

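RNA from the upper part of untreated wheat seedlings without roots, 2 months after germination, was extracted with Trizol, and 1 µg per sample went into libraries made with the NEBNext Ultra RNA kit, per the labels. There were 12 libraries, 3 each from wild type (WT) and the TaSIP1ΔC overexpression lines C20, C22 and C40, the last also written 40C in the labels. The authors deposited raw counts per gene, made with featureCounts 1.5.0-p3, and FPKM values per gene. The aligner, genome build, annotation release and strand setting are not given in the sources used here. Checked on the values, each FPKM was the count over gene length times 1 constant per library, and the constants differed from 1 over the library total by factors of 0.797 to 1.35, so the deposited FPKM values were rescaled between libraries. The count table held 124118 genes, of which 13328 had identifiers outside the reference style, and 75592 had a Pfam domain description.

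Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 75788, of which 64.2% were described. Libraries were scaled by TMM, and a quasi-likelihood model with 4 group means was fitted to all 12. The contrasts were the mean of the 3 lines against WT, each line against WT, an F test for any difference between lines, and each line against the mean of the other lines. Genes were called at an adjusted p (Benjamini-Hochberg) of at most 0.05. Standard errors are the absolute log2 fold change over the square root of the F statistic. The median biological coefficient of variation was 0.396. CPM values are counts relative to the TMM-scaled library total, on the usual CPM scale. Library totals ranged from 25622422 to 43532179 counts. Folds against a group with 0 counts are lower bounds against a floor of 3 counts over the group, and ratios of groups with 1 to 3 counts carry 95% counting intervals.

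Before the data were examined, 34 gene lists were fixed as text patterns for descriptions. The patterns for circadian, type II NAD(P)H dehydrogenase, OM66, UDP-glycosyltransferase and floral MADS genes matched too few tested genes for a test, and 29 lists were tested. A further 16 lists were written from the Pfam vocabulary of the table after it was seen and before any test, and 15 of them were tested, the gliadin and lipid transfer list having 0 tested genes. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation. All 1330 Pfam domains with at least 10 tested genes were also tested. By camera, 8 fixed lists were higher and 10 lower in the mean of the lines, and 3 and 5 of the added lists. With an estimated correlation 0 passed.

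Named genes followed a rule fixed before the data were examined. It took the 10 described genes with the largest rise and the 10 with the largest fall in the mean of the lines among those called, with a mean of at least 2 CPM in the higher group and all 9 line libraries on the same side of all WT libraries. It also took up to 3 members of each list with the lowest adjusted p, 3 rising and 3 falling genes per line, and every alternative oxidase and SRO gene. The part of this set named in the text was chosen after the values were seen. The share of changed genes per chromosome was compared with the rest by Fisher's exact test, two-sided, over 22 sequences. The segment of 2A was delimited after that result was seen.

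Replicates were compared before averaging, and the chi-square per gene of replicate pairs was 7.21 to 183, so none agreed within sampling noise. Replicate numbers were not taken as pairs, since residual profiles of the 18 pairs with the same number correlated at r between -0.51 and 0.461 and only 8 of these pairs exceeded 0.1. The pairs numbered 2 were all positive (0.0910 to 0.461), and 4 libraries were closest to one with their own number, so a replicate block was kept as an alternative. The methods were tested on simulated data with 100 changed genes per fold. For the mean of the lines edgeR recovered 8% of 2-fold and 77% of 4-fold changes with 5 false calls, and for 1 line 1% and 35% with 1 false call. DESeq2 1.42.0 recovered 32% and 96% with 103 false calls, and limma on FPKM 8% and 75% with 7. A simulated raised list had an adjusted p of 8.97e-133, but random lists, whose genes share no correlation, do not test the preset correlation.

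The alternatives were RLE size factors, DESeq2, no filter, a filter of 1 CPM in 3 libraries, a replicate block, limma on log2(FPKM + 0.1), a log2 fold change of at least 1, each line fitted with WT alone, the fry rotation test, an estimated correlation, and leaving out each library in turn. After seeing the data, 2 were added: the mean log2 CPM of the histone and cell-cycle list as a covariate, and leaving out C20 replicate 3 and C40 replicate 1 together.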

Results

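The transcriptome of the upper part of untreated wheat seedlings, collected without roots at an age of 2 months, was measured by RNA sequencing. The series compared wild type (WT) with 3 transgenic lines, C20, C22 and C40, that overexpress TaSIP1 in a form marked ΔC in the labels. The title of the series places TaSIP1 in signalling from the mitochondrion to the nucleus, where it is held back by its partner TaSRO1. Each of the 4 groups had 3 libraries. Gene counts summed to 43532179, 37757184 and 39980964 in WT replicates 1, 2 and 3, to 28318925, 27274952 and 29574512 in those of C20, to 29113955, 25622422 and 38454215 in those of C22, and to 31028886, 26632177 and 26547959 in those of C40. The labels do not say that the replicates came from separate plants, so the p-values measure the spread between these samples, which may be technical. Whether strand was used in counting is not given in the sources used here, so overlapping and antisense genes are uncertain, and so are near-identical homoeologs that share reads. Positions are those of the count table, whose genome build is not given in the sources used here. Counting intervals and floors cover counting error only.

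The libraries of WT and C22 were uniform and those of C20 and C40 were not. Across genes, log2 CPM, the counts scaled to library size, correlated at r between 0.953 and 0.978 within WT and between 0.949 and 0.968 within C22, against 0.858 to 0.955 within C40 and 0.743 to 0.891 within C20. Genes are not independent replicates in these values. The first principal component carried 48.4% of the variance. On that axis C20 replicate 3 and C40 replicate 1 lay nearer to WT than the other 7 line libraries did. The same 2 libraries stood apart in transcripts of cell division. The summed level of the histone and cell-cycle genes was 1502 to 1870 CPM in WT, 2109 CPM in C20 replicate 3 and 1703 CPM in C40 replicate 1, and 6188 to 14924 CPM in the other 7 line libraries. The Rubisco small subunit genes took 3.83% to 4.64% of the raw counts in WT and 1.19% to 3.63% in the lines. In TMM-scaled CPM the ranges overlapped, with 45856 to 63605 CPM in WT and 9607 to 48281 CPM in the lines.

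**Figure D1:**
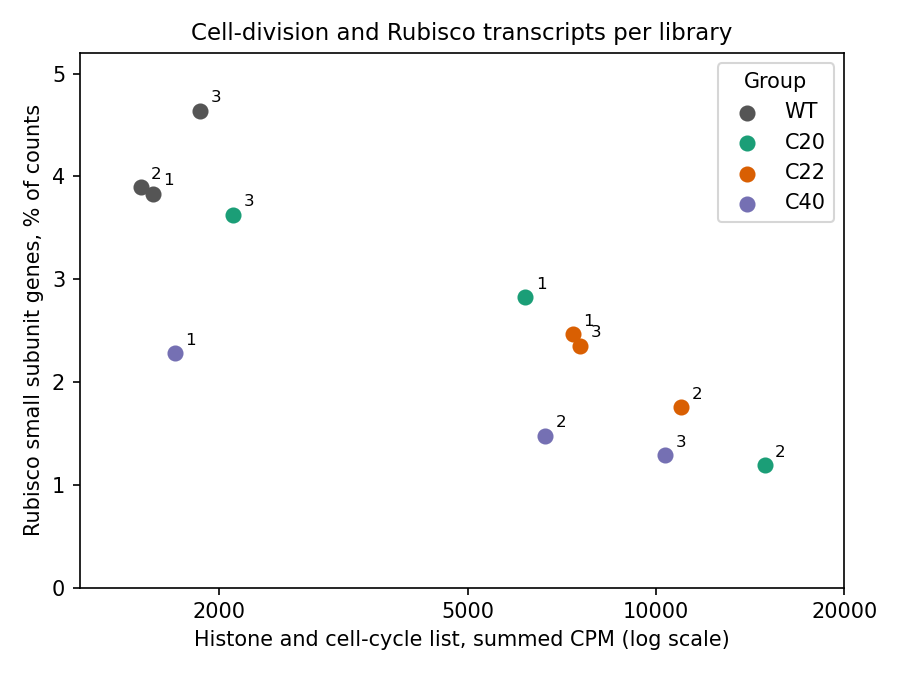
Each point is 1 library (number, replicate), with the summed CPM of the histone and cell-cycle genes on a log axis and the percent of raw counts from Rubisco small subunit genes on the vertical axis. WT lies between 1502 and 1870 CPM, while 7 of the 9 line libraries lie between 6188 and 14924 CPM.

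The first comparison, the mean of the 3 lines against WT, asked what the lines had in common. By camera with its preset correlation, lists of cell division, ribosomal proteins, chaperones, defence and alternative oxidase were higher in the lines, and lists of photosynthesis, flavonoid and jasmonate genes were lower, but 0 lists passed with an estimated correlation between genes. With the cell-division level as a covariate, chosen after seeing the data, the lists of ribosomal proteins (adjusted p = 0.951) and chaperones (0.204) did not pass. The photosystem list was then higher, not lower (0.0224). On this covariate WT lay below every line library (-1.09 to -0.95, against -0.37 or more), so all results adjusted for it are extrapolated. Of 13 alternative oxidase genes 7 rose, all with close identifiers within 2A, 2B or 2D. The largest rise was that of TraesCS2A01G438200, from 1.09 ± 0.123 CPM in WT (SD, n = 3) to 24.2 ± 20.1 CPM in the lines (SD, n = 9). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 17592 of 75788 genes changed, of which 8691 rose and 8901 fell. At least a 2-fold difference was estimated for 6734 of those that rose and 5019 of those that fell. All 9 line libraries lay above all 3 WT libraries for 5.95% of the genes and below them for 8.13%. Chance gives 0.455% each if all libraries are exchangeable, but the 9 came from 3 lines. Genes also move together, so the excess over that value does not exclude chance. The count of 17592 changed genes rested on the WT libraries: it was 6426, 4216 and 5828 without WT replicate 1, 2 or 3, and 26498 without C20 replicate 3. The balance of rises and falls is not settled. Without WT replicate 1, 2 or 3, 2045, 1218 and 1812 genes rose and 4381, 2998 and 4016 fell, and falls also led without C20 replicate 1 (6168 rose, 7769 fell), without C22 replicates 1, 2 and 3 (5948 and 7152, 5478 and 6651, 5775 and 6936), without C40 replicates 2 and 3 (6216 and 7315, 5714 and 6859) and with the replicate block (7075 and 8939). Rises led with DESeq2 (13541 and 11471), with the cell-division covariate (2372 and 1434) and at a log2 change of at least 1 (6734 and 5019). Without C20 replicate 3 and C40 replicate 1, an alternative chosen after seeing the data, 32263 genes changed.

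Alternative oxidase, the ubiquinol oxidase that bypasses complexes III and IV of the respiratory chain and whose induction is a common readout of mitochondrial retrograde signalling, had 13 tested genes. Of these, 7 rose, 0 fell and 6 did not pass, and 7 rose and 0 fell when adjusted over the list alone. The 7 have close identifiers within 2A, 2B or 2D, so they may be neighbours and homoeologs that share reads, not 7 separate responses. TraesCS2A01G439400, also close by identifier, did not pass (0.23 on the log2 scale). Members further off by identifier on 2A, 2B and 2D (-0.38, 0.27 and -0.10) and those on 6A and 6B (-0.95 and -0.49) did not pass either. TraesCS2A01G438200 (2A, 689630253 to 689631640) rose by 4.31 ± 0.64 on the log2 scale (SE, adjusted p = 0.00281), its neighbour TraesCS2A01G438300 by 3.62 ± 0.66 (adjusted p = 0.00604) and TraesCS2D01G436200 by 3.61 ± 0.69 (adjusted p = 0.00733). On 2B, TraesCS2B01G459100 rose from 5.27 ± 1.0 to 34.3 ± 24.4 CPM and TraesCS2B01G459000 from 7.12 ± 2.49 to 36.2 ± 31.8 CPM. The smaller rises were those of TraesCS2B01G459300, by 1.19 on the log2 scale, and TraesCS2D01G436700, by 1.07. The lowest line library had 6.58 CPM of TraesCS2A01G438200, above every WT library. The highest values of that gene, 71.3 CPM, came from C20 replicate 3, a library with WT-like histone levels. Of the 6 that did not pass, the most abundant was TraesCS2D01G542600, with 49.6 ± 5.69 CPM in WT and 46.2 ± 19.2 CPM in the lines, and TraesCS6A01G269100 had a log2 change of -0.95 (adjusted p = 0.115). Without C20 replicate 2 or 3 that gene fell, by 0.79 (adjusted p = 0.00815) and 1.18 (adjusted p = 0.0336). Summed over the 13 genes, WT had 134 to 161 CPM, and 2 line libraries lay below, C20 replicate 2 at 67.7 CPM and C22 replicate 2 at 116 CPM. By the mean of log2 CPM, C20 replicate 2 alone lay below WT (1.92, against 2.09 to 2.44), and C22 replicate 2 lay above (2.71). Over the whole list, the camera test gave an adjusted p of 0.0353, and the adjusted p was 0.716 with an estimated correlation between genes and 0.310 with the fry test. The list also did not pass without WT replicate 1 (0.0516), C20 replicate 1 (0.0589), C20 replicate 3 (0.112) or C40 replicate 1 (0.0834), or without C20 replicate 3 and C40 replicate 1 together (0.219), and it passed with the cell-division covariate (5.23e-06). TraesCS2A01G438200 passed without each library in turn. Without WT replicate 1, 2 or 3 TraesCS2B01G459000 did not pass, with adjusted p = 0.0864, 0.0849 and 0.0594, nor did TraesCS2B01G459100 without WT replicate 2 (adjusted p = 0.0519). TraesCS2B01G459300 had adjusted p = 0.0973, 0.134 and 0.103 without the WT replicates in turn, 0.0574 without C20 replicate 1 and 0.0539 without C40 replicate 2. TraesCS2D01G436700 had 0.115, 0.175 and 0.137 without the WT replicates, 0.0744 and 0.0534 without C20 replicates 1 and 3, 0.0508 without C22 replicate 3, and 0.0722 and 0.0739 without C40 replicates 2 and 3.

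**Figure D2:**
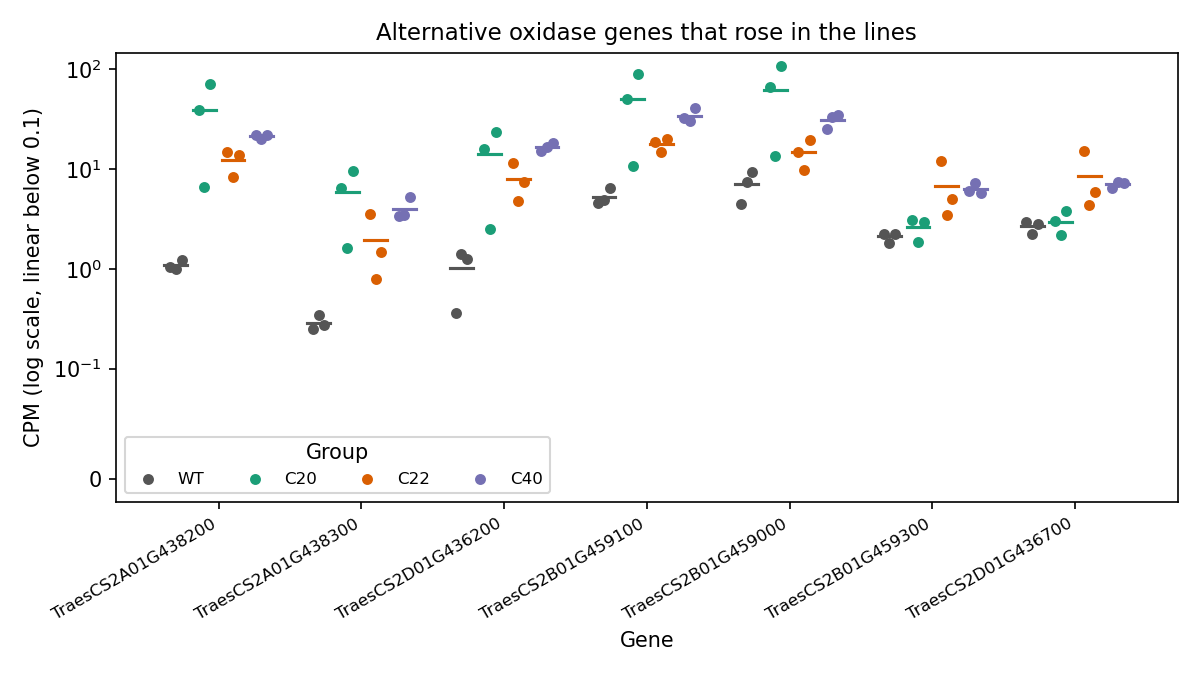
Points are CPM per library (log axis, linear below 0.1) of the 7 alternative oxidase genes that rose, and bars are group means (n = 3). TraesCS2A01G438200 lies near 1.09 CPM in WT and at 6.58 CPM or more in each of the 9 line libraries.

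Other lists of mitochondrial and redox genes were tested. Of 61 tested genes for mitochondrial carriers and import (TIM and TOM) proteins, 18 rose and 8 fell (camera adjusted p = 0.0173, adjusted p = 0.653 with an estimated correlation; 25 and 8 adjusted over the list alone), and the list did not pass with fry (0.0890) or with the cell-division covariate (0.826). In summed level this list was 444 to 517 CPM in WT and lower in every library of C22 and C40 (376 to 440 CPM). C20 had 453 to 549 CPM. By the mean of log2 CPM all line libraries lay above WT (1.93 to 2.49, against 1.78 to 1.84). Of 56 respiratory chain genes, 0 rose and 3 fell (adjusted p = 0.774, and 0.909 with an estimated correlation; 0 and 0 adjusted over the list alone), and with the covariate the list was lower in the lines (0.0120). Among 44 genes with the domain of BCS1- and OM66-type AAA ATPases, 4 rose and 0 fell (adjusted p = 0.425, and 0.957 with an estimated correlation), including TraesCS2A01G221300 with a rise of 2.83 ± 0.45 on the log2 scale (adjusted p = 0.00372). The RST domain, found in SRO proteins such as TaSRO1 and in TAF4 proteins, was present in 18 tested genes. Of these 1 fell, TraesCS6A01G242900, by 0.51 on the log2 scale (adjusted p = 0.0406), and 0 rose (list adjusted p = 0.858, and 0.957 with an estimated correlation). The list written for SRO proteins also took in Rcd1-like genes of another family, and of its 26 tested genes 0 rose and 2 fell (adjusted p = 0.722, and 0.788 with an estimated correlation; 0 and 0 adjusted over the list alone). Of 43 antioxidant enzyme genes, 4 rose and 5 fell (adjusted p = 0.0299, and 0.653 with an estimated correlation; 4 and 5 adjusted over the list alone). That list did not pass without WT replicate 1 (0.0534), with fry (0.135) or with the covariate (0.840). The peroxiredoxin gene TraesCS2B01G313700 fell from 588 ± 22.7 to 269 ± 113 CPM. Of 223 glutathione transferase genes, 46 rose and 32 fell (adjusted p = 0.182, and 0.788 with an estimated correlation; 56 and 34 adjusted over the list alone), among them TraesCS5D01G030000, which rose by 2.33 ± 0.35 on the log2 scale, and TraesCS2D01G044100, which rose from 0.0415 ± 0.0187 to 3.24 ± 2.5 CPM. The glutathione transferase list was higher without C20 replicate 2 (0.0312) and with the covariate (0.00532). Its summed level was 3290 to 3752 CPM in WT. C20 replicate 3 (4108 CPM) lay above that, C22 replicate 1 (3518 CPM) within it and the other line libraries below. By the mean of log2 CPM C20 replicate 2 lay below WT (1.03, against 1.30 to 1.37) and the other line libraries above. The covariate results for these lists are extrapolated, since WT lay below every line library on it.

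Many cell-division genes rose. Of 361 tested histone and cell-cycle genes, 275 rose and 3 fell (camera adjusted p = 2.09e-11, adjusted p = 0.653 with an estimated correlation; 312 and 7 adjusted over the list alone). Among described genes that averaged at least 2 CPM in the lines and lay above WT in all 9 line libraries, the 10 with the largest fitted rises were all core histone genes. TraesCS1A01G038200, an H2A gene, had 0 counts in all of WT and a mean of 93.5 ± 68.8 CPM in the lines (n = 9), at least 3171-fold higher against a floor of 3 counts over the WT group (adjusted p = 0.017). By the same floor TraesCS5D01G252700 was at least 1513-fold and TraesCS1A01G274300 at least 1277-fold higher. In C20 replicate 3 and C40 replicate 1 these 3 genes had at most 1.17 CPM. Histone genes are many and near-identical, and reads that fit several copies may have been divided among them, so the value of a single copy is uncertain. Of 635 ribosomal protein genes, 211 rose and 73 fell (adjusted p = 9.37e-14, and 0.653 with an estimated correlation; 421 and 79 adjusted over the list alone). The summed ribosomal level did not separate the groups, with 16812 to 21468 CPM in WT. C40 replicate 1 (15429 CPM) and C22 replicate 3 (16137 CPM) lay below that, C22 replicates 1 and 2 (17049 and 19083 CPM) within it, and the other line libraries above, with 33918 CPM in C20 replicate 2. By the mean of log2 CPM over the list, C40 replicate 1 (3.44) lay within WT (2.95 to 3.50). All other line libraries lay above it (3.59 to 4.46). Of 81 Hsp70 and Hsp90 chaperone genes, 31 rose and 2 fell (adjusted p = 1.47e-06, and 0.805 with an estimated correlation), for example the Hsp90 gene TraesCS5B01G106300, by 0.99 ± 0.16 on the log2 scale, and the Hsp70 gene TraesCS1D01G121000, by 1.64 ± 0.32. The wider chaperone list, which also held unrelated ATPases, had 45 that rose and 20 that fell among 203 (adjusted p = 0.0223, and 0.653 with an estimated correlation; 51 and 21 adjusted over the list alone). With the cell-division level of each library as a covariate, chosen after seeing the data, 3806 genes changed in place of 17592, and the histone and cell-cycle list, from which the covariate is computed, had an adjusted p of 0.0598. With fry the histone and ribosomal lists did not pass (0.240 and 0.0781).

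Many defence genes rose in the mean of the lines. The summed levels, in which abundant genes weigh most, were above WT in some libraries only. Means of log2 CPM, which weigh genes alike, set more libraries above WT for the WRKY and pathogenesis-related lists. Of 199 WRKY transcription factor genes, regulators of immune and stress responses, 64 rose and 14 fell (camera adjusted p = 1.76e-04, adjusted p = 0.653 with an estimated correlation; 83 and 16 adjusted over the list alone). TraesCS3A01G116200 rose from 0.141 ± 0.0493 to 2.54 ± 1.91 CPM, TraesCS1A01G410700 from 0.328 ± 0.0397 to 5.91 ± 4.52 CPM and TraesCS1D01G418600 from 0.0804 ± 0.0257 to 2.74 ± 1.69 CPM. Of 141 pathogenesis-related genes, 26 rose and 11 fell (adjusted p = 0.0321, and 0.653 with an estimated correlation; 26 and 11 adjusted over the list alone), including the thaumatin-type gene TraesCS7A01G558500, from 0.472 ± 0.111 to 60.4 ± 41.1 CPM, and the chitinase gene TraesCS5B01G403700, from 0.183 ± 0.0421 to 34.1 ± 25.9 CPM. This list did not pass without WT replicate 2 (0.0537), C20 replicate 3 (0.0527) or C40 replicate 2 (0.0635). A second list of PR-1, glucanase, class III chitinase and barwin genes had 50 that rose and 14 that fell among 188 (adjusted p = 0.0198, and 0.805 with an estimated correlation). Its PR-1-type genes TraesCS5A01G183300 and TraesCS5B01G181500 rose by 7.18 ± 0.80 and 7.49 ± 0.89 on the log2 scale. TraesCS7D01G201400 rose by 6.49 ± 0.77. The lowest line library had 3.34 CPM of TraesCS5A01G183300, against 0.327 ± 0.102 CPM in WT. Of 946 NB-ARC immune receptor genes, 82 rose and 72 fell (adjusted p = 0.858, and 0.957 with an estimated correlation). Jasmonate synthesis and response genes went the other way, with 2 that rose and 26 that fell among 129 (adjusted p = 0.00207, and 0.653 with an estimated correlation; 2 and 26 adjusted over the list alone). The lipoxygenase gene TraesCS6B01G193400 fell from 74.5 ± 1.09 to 15.2 ± 6.18 CPM. The summed WRKY level was 944 to 1233.6 CPM in WT, 2823 and 4061 CPM in C20 replicates 1 and 3 and 1619 to 1808 CPM in C40, but 844 CPM in C20 replicate 2, below all of WT, and 1004 to 1317 CPM in C22. By the mean of log2 CPM over the list, every line library lay above WT (0.475 to 0.618). C20 replicate 2 was at 0.636 and C22 at 0.920 to 1.28. The second defence list had 1021 to 1219 CPM in WT, 848 CPM in C20 replicate 2 and 1200 to 1231 CPM in C22, against 1510 and 1933 CPM in C20 replicates 1 and 3 and 2084 to 2162 CPM in C40. The pathogenesis-related list had 955 to 1122 CPM in WT, and C20 replicate 2 and C22 replicates 1 and 3 did not exceed that (1035, 1034 and 950.2 CPM). By the mean of log2 CPM only C20 replicate 2 did not exceed WT (0.549, against 0.369 to 0.619). The jasmonate list in C20 replicate 3 was within WT, at 5037 CPM against 4772 to 5530 CPM. By the mean of log2 CPM that library lay below WT (3.04, against 3.20 to 3.45). On that scale C20 replicate 1 lay above WT (3.51), C40 replicates 2 and 3 within it (3.44 and 3.35), and the rest below. With fry the lists of WRKY (0.240), pathogenesis-related (0.278) and jasmonate genes (0.103) did not pass.

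Many photosynthesis genes fell. All 18 Rubisco small subunit genes were tested, and 14 fell and 0 rose (adjusted p = 1.99e-07, and 0.805 with an estimated correlation), with a median log2 change of -1.61. TraesCS2A01G067200 fell from 840 ± 196 to 179 ± 173 CPM, TraesCS2D01G065400 from 831 ± 240 to 192 ± 173 CPM and TraesCS2B01G079400 from 1139 ± 188 to 291 ± 225 CPM. Of 57 Calvin cycle genes, 31 fell and 0 rose (adjusted p = 1.89e-11, and 0.653 with an estimated correlation; 38 and 0 adjusted over the list alone). The list of photosystem and light-harvesting genes had 31 that fell and 4 that rose among 160 (adjusted p = 9.41e-11, and 0.653 with an estimated correlation; 30 and 4 adjusted over the list alone), and the 96 chlorophyll a/b-binding genes alone had 16 that fell and 0 that rose (adjusted p = 2.96e-08, and 0.805 with an estimated correlation). One of these, TraesCS5B01G218200, fell by 1.70 ± 0.25 on the log2 scale. CCT-domain genes, the family of CONSTANS-like and clock-associated regulators, had 27 that fell and 2 that rose among 84 (adjusted p = 2.96e-08, and 0.805 with an estimated correlation). TraesCS1D01G452200 fell from 39.6 ± 1.55 to 14.1 ± 3.8 CPM and TraesCS2B01G140300 from 17.7 ± 3.28 to 3.85 ± 2.66 CPM. With the cell-division covariate the photosystem list was higher in the lines, not lower (adjusted p = 0.0224). This direction is extrapolated, since WT lay below every line library on the covariate. With fry the photosystem list did not pass (0.138). C20 replicate 3 lay above all WT libraries in the summed level of that list, with 191198 CPM against at most 183606 CPM, and in the share of counts from light-harvesting genes, with 9.57% against at most 8.99%.

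The same rule named the 10 described genes with the largest falls. TraesCS3D01G077400, a cytochrome P450 gene, fell from 25.5 ± 6.6 to 0.134 ± 0.22 CPM, or by 8.36 ± 0.63 on the log2 scale (adjusted p = 1.73e-04). On the short arm of 2A, TraesCS2A01G021900, of the chalcone and stilbene synthase family, and its neighbour TraesCS2A01G021800, an alpha/beta hydrolase gene, fell by 7.85 and 7.74 on the log2 scale. TraesCS2A01G035300, also of the chalcone and stilbene synthase family, fell by 6.65. Neighbouring genes on 4A for a FAE1-type condensing enzyme, TraesCS4A01G303900, and an acyl transferase-type protein, TraesCS4A01G304000, changed by -6.67 and -6.54 on the log2 scale, and the former reached 21.4 CPM in its highest line library against a WT mean of 39.7 ± 7.22 CPM. The others were a gene of the fatty acyl reductase-like male sterility family (1A, 8041058 to 8045258), which fell by 7.18, an AMP-binding enzyme gene, TraesCS5B01G365000, by 6.98, a terpene synthase gene, TraesCS2B01G445900, by 6.48, and a pyridoxal-dependent decarboxylase gene, TraesCS6D01G014100, by 6.35. Of 61 phenylpropanoid and flavonoid genes, 32 fell and 1 rose (adjusted p = 7.43e-07, and 0.556 with an estimated correlation; 36 and 1 adjusted over the list alone). TraesCS2B01G019200, of the chalcone and stilbene synthase family, fell from 43.4 ± 2.72 to 5.73 ± 11.4 CPM. Of 649 cytochrome P450 genes, 156 fell and 81 rose (adjusted p = 0.0156, and 0.653 with an estimated correlation; 175 and 99 adjusted over the list alone). One of them, TraesCS2A01G022800, fell by 5.54 ± 0.44 on the log2 scale. The P450 list did not pass without C20 replicate 2 (0.0906) or with fry (0.109), and with the covariate its direction turned (0.455). The median of that list was -0.20 and its mean 0.15 on the log2 scale. MATE transporter genes, identified by their domain, had 25 that fell and 6 that rose among 124 (adjusted p = 1.32e-04, and 0.805 with an estimated correlation), for example TraesCS7B01G137200, from 102 ± 37.1 to 16.2 ± 16.1 CPM. Of 437 UDP-glycosyltransferase genes, 91 fell and 60 rose (adjusted p = 0.0373, and 0.849 with an estimated correlation).

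**Figure D3:**
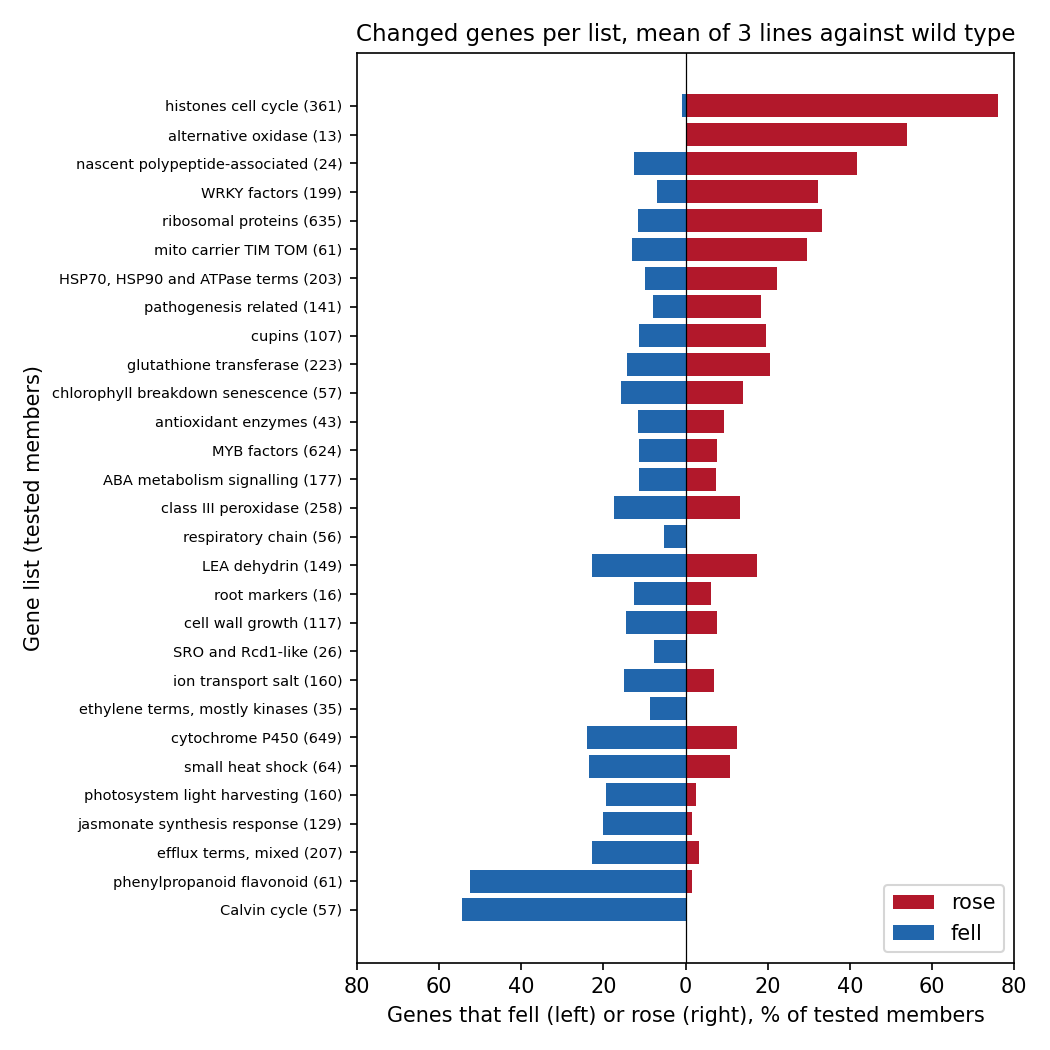
For each list fixed before the data were examined, bars give the percent of tested members that rose (right) or fell (left) in the mean of the 3 lines against WT by edgeR. The histone and cell-cycle list has 275 of 361 genes that rose, and the Calvin cycle list 31 of 57 that fell.

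Salt-related lists showed members moving both ways. In summed level, ion transport genes were lower in every line library (2016 to 3777 CPM) than in WT (3830 to 3981 CPM). The same held for small heat shock genes (151 to 292 CPM, against 443 to 554 CPM). By the mean of log2 CPM, line libraries lay on both sides of WT for each of these lists. Of 160 ion transport genes, 11 rose and 24 fell (adjusted p = 0.182, and 0.788 with an estimated correlation; 10 and 21 adjusted over the list alone). The sodium/hydrogen exchanger gene TraesCS5B01G031800 had 0 counts in WT and 1.03 ± 0.843 CPM in the lines, at least 36.6-fold higher, and the potassium transporter gene TraesCS2D01G419000 fell from 22.1 ± 1.06 to 11.7 ± 0.985 CPM. Of 149 late embryogenesis abundant and dehydrin genes, 26 rose and 34 fell (adjusted p = 0.128, and 0.788 with an estimated correlation; 32 and 36 adjusted over the list alone). Of 177 abscisic acid genes, 13 rose and 20 fell (adjusted p = 0.499, and 0.788 with an estimated correlation; 13 and 18 adjusted over the list alone). Small heat shock protein genes had 7 that rose and 15 that fell among 64 (adjusted p = 0.0142, and 0.653 with an estimated correlation; 9 and 16 adjusted over the list alone), with a median of -0.42 and a mean of 0.02 on the log2 scale. The small heat shock list did not pass without C20 replicate 3 (0.0527), or without it and C40 replicate 1 together (0.110).

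The NAC transcription factor family was chosen before the data were examined as a check for the overexpressed gene, but the labels do not say to which family TaSIP1 belongs. The fixed pattern for this family matched other genes, so a list by domain, added after the descriptions were seen, took its place. Of its 206 tested genes, 30 rose and 20 fell, and 34 rose and 22 fell when adjusted over the list alone. The list as a whole did not pass (adjusted p = 0.698, and 0.957 with an estimated correlation). The lowest adjusted p-values were those of TraesCS5A01G143100 (rise of 2.48 ± 0.37 on the log2 scale, adjusted p = 0.00279), TraesCS5B01G141900 (2.22 ± 0.33, adjusted p = 0.00288) and TraesCS6A01G208900 (1.86 ± 0.31, adjusted p = 0.00432), none of which exceeded 5.49 CPM in any library. Among abundant members, chosen after their values were seen, the group 5 genes TraesCS5B01G480900 and TraesCS5D01G481200 rose by 1.38 and 1.75 on the log2 scale (adjusted p = 0.0286 and 0.0219), and TraesCS5A01G468300 had a log2 change of 1.18 (adjusted p = 0.0536). The highest value of each, 198, 219 and 179 CPM, came from C20 replicate 3. No identifier in the labels ties any of these genes to the transgene, so the level of TaSIP1 itself was not analysed here. Without WT replicate 1, 2 or 3 the count of 50 changed genes fell to 17, 16 and 21. With the cell-division covariate 25 rose and 0 fell.

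Among other regulators and defence-related lists, 47 of 246 AP2-domain genes rose and 17 fell (adjusted p = 0.0373, and 0.805 with an estimated correlation), and 48 of 624 MYB genes rose and 71 fell (adjusted p = 0.163, and 0.653 with an estimated correlation; 43 and 68 adjusted over the list alone). Of 77 MADS-box genes 15 rose and 10 fell (adjusted p = 0.178, and 0.805 with an estimated correlation), and of 54 heat shock factor genes 7 rose and 8 fell (adjusted p = 0.545, and 0.904 with an estimated correlation). Of 258 class III peroxidase genes 34 rose and 45 fell (adjusted p = 0.551, and 0.823 with an estimated correlation; 36 and 47 adjusted over the list alone). Cell wall growth genes had 9 that rose and 17 that fell among 117 (adjusted p = 0.0156, and 0.653 with an estimated correlation; 9 and 17 adjusted over the list alone). This list did not pass without WT replicate 1 (0.0788), WT replicate 2 (0.0821) or C20 replicate 3 (0.0768), without C20 replicate 3 and C40 replicate 1 together (0.187) or with fry (0.103). Expansin and xyloglucan transferase genes had 23 and 19 among 146 (adjusted p = 0.858, and 0.957 with an estimated correlation). Chlorophyll breakdown and senescence genes had 8 that rose and 9 that fell among 57 (adjusted p = 0.137, and 0.788 with an estimated correlation; 9 and 11 adjusted over the list alone). Markers of root had 1 and 2 among 16 (adjusted p = 0.748, and 0.845 with an estimated correlation; 1 and 2 adjusted over the list alone), and seed storage-type cupin genes 21 and 12 among 107 (adjusted p = 0.337, and 0.743 with an estimated correlation; 23 and 12 adjusted over the list alone). The pattern for NAC factors matched nascent polypeptide complex genes, of which 10 rose and 3 fell among 24 (adjusted p = 0.00109, and 0.653 with an estimated correlation; 11 and 3 adjusted over the list alone). That for AP2/ERF factors matched mostly kinases, with 0 and 3 among 35 (adjusted p = 0.0198, and 0.653 with an estimated correlation; 0 and 1 adjusted over the list alone), and that for MATE efflux a mixed set with 7 and 47 among 207 (adjusted p = 3.27e-05, and 0.653 with an estimated correlation; 7 and 49 adjusted over the list alone). With the covariate these 3 lists did not pass (0.503, 0.808 and 0.315), and with fry the AP2/ERF pattern did not (0.0690) while the MYB list did (0.00625).

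The lines were then compared with WT singly. In C20, 1862 genes changed (1089 rose, 773 fell), in C22 13666 (7181 rose, 6485 fell) and in C40 14103 (7432 rose, 6671 fell). With limma on FPKM more genes fell than rose, at 834 and 1004 for C20 (rose, fell), 5761 and 7096 for C22, and 5544 and 7287 for C40. More fell than rose in each line without any 1 of the WT replicates. Without WT replicate 1 it was 36 and 63 for C20 (rose, fell), 1700 and 3150 for C22, and 2706 and 3416 for C40, without replicate 2 it was 26 and 61, 1124 and 2264, and 2058 and 2561, and without replicate 3 it was 61 and 90, 1907 and 3515, and 2700 and 3378. The same held in C22 with RLE size factors (6767 and 6860), in C22 and C40 with a replicate block (5758 and 6133, and 5995 and 6456), in both without C20 replicate 1 (5275 and 6002, and 5772 and 5973), and in C22 without C22 replicate 2 (2025 and 2068) or 3 (2812 and 2878) or C40 replicate 2 (5419 and 5509). It also held with WT alone beside the line in C20 (4 and 8) and C40 (9203 and 9303). The balance of rises and falls is therefore not settled for any line. DESeq2 gave 11861, 20840 and 21535 genes for C20, C22 and C40. With the cell-division covariate 2133, 2926 and 7484 genes changed, and with a replicate block 982, 11891 and 12451. In all 3 lines the same 1178 genes changed in the same direction, 756 up and 422 down, against 695 with the replicate block and 6483 with DESeq2. The shared count rests on the joint fit of the 4 groups. With C20 fitted beside WT alone 12 genes changed in C20, so separate fits could share at most 12. The excess of shared rises was absent with limma on FPKM (578 up, 589 down) and without WT replicate 1 (33 and 46), 2 (23 and 40) or 3 (54 and 59). Independent lists of these sizes would share 10.1 and 5.82 genes, a number that leaves out what the common WT libraries add. Across genes, log2 fold changes correlated at r = 0.824 between C20 and C22, 0.812 between C20 and C40, and 0.898 between C22 and C40, with covariances of 2.0, 1.97 and 2.51. In 10 simulations all 12 libraries, WT included, were drawn gene by gene with no group difference and the same spread in each group. There the mean r was 0.499 and the mean covariance 0.158, from the sharing of a simulated WT group. The real groups differed in spread, so these values do not measure what the real WT libraries add. The 3 WT libraries are too few to be split between comparisons, so part of the excess in shared genes may come from them. The C20 count was 99, 87 and 151 without WT replicates 1, 2 and 3, 374, 3931 and 12749 without C20 replicates 1, 2 and 3, 763, 1007 and 678 without C22 replicates 1, 2 and 3, and 5412 and 864 without C40 replicates 1 and 2, and with only C20 and WT in the fit 12 genes changed. With only C22 and WT it was 30005 genes. The C22 count was 4850, 3388 and 5422 without the WT replicates in turn, 22299 without C20 replicate 2, and 5542, 4093 and 5690 without the C22 replicates in turn. The C40 count was 6122, 4619 and 6078 without the WT replicates in turn, 22910 without C20 replicate 2, and 7186 and 4288 without C40 replicates 2 and 3. The shared count was 79, 63 and 113 without the WT replicates in turn, 308, 2268 and 6739 without those of C20, 455, 530 and 397 without those of C22, and 3359, 545 and 638 without those of C40. Among the gene lists, 5 were higher and 10 lower in C20, 4 and 10 in C22, and 9 and 5 in C40 by camera, and 0 with an estimated correlation.

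Single genes named for a line differed there from WT and from the mean of the other lines, which does not exclude a change in those. C20 had 5.82 ± 0.05 CPM of a gene with a MAP65 microtubule-binding domain (2D, 364950046 to 364955564), against 0.0393 ± 0.0342 CPM in WT, and more of TraesCS6A01G363200 (10.6 ± 9.86 CPM) and of a WRKY gene on 4B (11715449 to 11716859; 20.1 ± 13.8 CPM). It had 0.0763 ± 0.0417 CPM of TraesCS4B01G222300, for a subunit of the general transcription factor TFIIF, against 5.08 ± 1.5 CPM in WT, and less of the zinc transporter gene TraesCS7A01G420600 and the peptidase gene TraesCS6B01G189800, by 5.21 and 3.93 on the log2 scale. With only C20 and WT in the fit the MAP65-domain gene (adjusted p = 0.0386) and TraesCS4B01G222300 (0.0471) passed, and TraesCS6A01G363200 (0.118), the WRKY gene (0.113), TraesCS7A01G420600 (0.0903) and TraesCS6B01G189800 (0.105) did not. In C22, the neighbouring 7B genes TraesCS7B01G253600, an aminotransferase gene, and TraesCS7B01G253700, a P450 gene, reached 35.0 ± 10.3 and 12.2 ± 2.76 CPM with 0 counts in WT, and the KNOX homeobox gene TraesCS4A01G256700 reached 7.13 ± 2.54 CPM, at least 237-fold higher than in WT. The transketolase-type gene TraesCS1A01G384300 fell from 30.01 ± 1.84 to 1.89 ± 0.554 CPM, the peptidase gene TraesCS3B01G283900 from 34.0 ± 4.76 to 2.36 ± 0.759 CPM, and a TPR repeat gene on 6D (388229349 to 388233373) from 2.54 ± 1.45 to 0.0289 ± 0.0319 CPM, from 3 counts, with a 95% counting interval of the ratio from 30.04 to 434. In C40, TraesCS7B01G253600 was also high (26.9 ± 8.06 CPM), and C20 had 0.785 CPM of it (adjusted p = 0.0308). C40 was high in the BURP-domain gene TraesCS7D01G021100 (115 ± 133 CPM) and the hydrophobic seed protein-type gene TraesCS2D01G409000 (13.5 ± 11.6 CPM). There, TraesCS6D01G014100 had 0.0212 CPM against 17.98 CPM in WT, from 2 counts, a ratio of 875 with a 95% counting interval from 242 to 7227, and this gene also fell in C20, to 2.37 CPM, and in C22, to 0.177 CPM. The glycosyltransferase gene TraesCS5D01G403800 had 0.0103 against 5.43 CPM, from 1 count, and the helix-loop-helix gene TraesCS5A01G533900 had 0.0212 against 6.47 CPM, from 2 counts, with intervals from 88.6 to 19628 and from 86.3 to 2590.5. Over all genes, 1890 differed between the 3 lines by an F test in edgeR. C20 differed from the mean of the other lines at 1728 genes, C40 at 1124 and C22 at 283. The count of 1890 was 674, 696 and 928 without the WT replicates in turn, 438 and 7390 without C20 replicates 1 and 2, 293, 409 and 408 without the C22 replicates, and 844 and 727 without C40 replicates 2 and 3. It was 656 with the replicate block, 8480 with DESeq2 and 6333 with the covariate.

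In the mean of the lines, in C20 and in C22, 0 of 22 sequences (21 chromosomes and the unplaced genes) had a share of changed genes that differed from the rest by Fisher's exact test. For the mean of the lines the calls of DESeq2 and of limma on FPKM also gave 0, but 1 chromosome passed without a filter, with the stricter filter and with the replicate block, and 2 with a log2 change of at least 1. It was 1 without WT replicate 1 or 2, C20 replicate 3, C22 replicate 2 or 3, or C40 replicate 2 or 3, it was 2 without WT replicate 3, and 3 without C20 replicate 2. The subgenomes A, B and D had 23.5%, 22.6% and 23.4% of their tested genes changed in the mean of the lines. C40 was the exception, since 25.2% of the tested genes on 2A changed against 18.2% elsewhere (adjusted p = 3.0e-25). The share on 2A was 12.6%, 10.5% and 13.1% without the WT replicates in turn, and 13.2% and 9.63% without C40 replicates 2 and 3, with an adjusted p of at most 2.9e-16 in these. Windows of 20 Mb, looked at after this result, placed the difference at the start of the chromosome. From the first gene to 143276770, 420 of 1047 tested genes fell and 33 rose in C40, while 18.9% of the genes on the rest of 2A changed. The median log2 difference from WT over the 658 genes there with a mean of at least 2 CPM was -0.95, -0.89 and -0.89 in C40 replicates 1, 2 and 3, and 0.04 in C20 and 0.01 in C22. The alternative oxidase genes of 2A lie outside this segment, but TraesCS2A01G021900, TraesCS2A01G021800, TraesCS2A01G022800, TraesCS2A01G035300 and TraesCS2A01G067200 lie inside it. Without this segment 13652 genes changed in C40. That count and those in the segment use rounded adjusted p-values, so together they slightly exceed the 14103 given for C40.

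**Figure D4:**
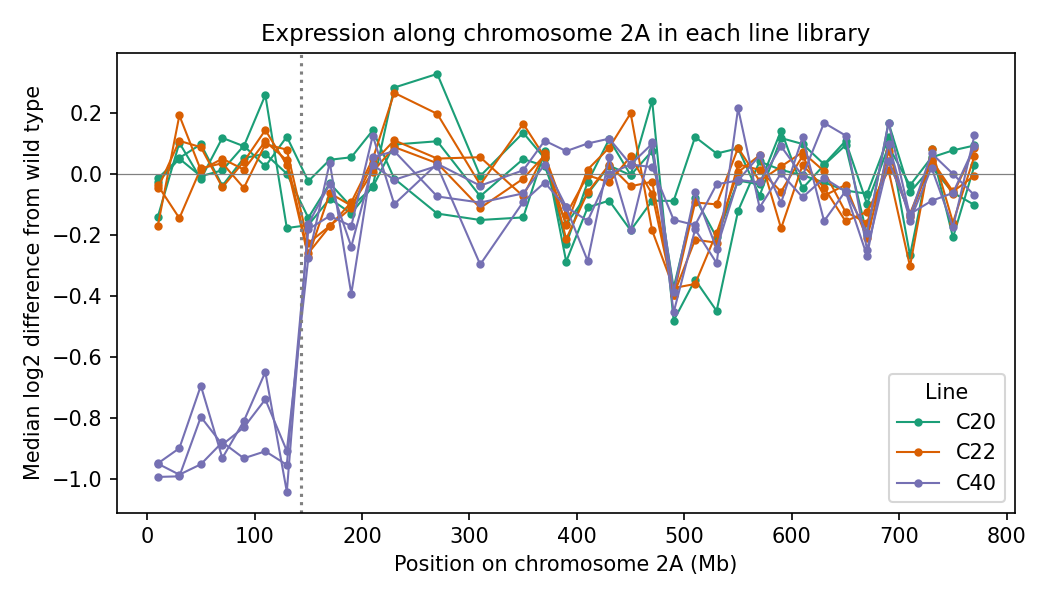
Points are medians over genes in 20 Mb windows of 2A of the log2 difference of each line library from the WT mean, against position in Mb. The 3 C40 libraries lie near -0.91 up to the dotted line at 143 Mb and near the other 6 beyond it.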

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

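The tests of library scaling, dividing tissue, a level fixed by the line, the 2A segment and the covariate for alternative oxidase were chosen after the results were seen, and the test of alternative oxidase against WRKY levels and the splits of the samples before.

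The lines differed from each other at 1890 genes by an F test in edgeR, and this difference between groups is why the following are listed. In 100 splits of the samples, 1 (the real one) gave as many, the highest other giving 57. A split that mixes the lines puts their differences into the spread within groups. Fewer calls there follow in part by construction and do not exclude chance. The count also ranged from 293 to 7390 when single libraries were left out. The adjusted p of the difference between lines was 0.00526 for TraesCS6D01G014100, 0.0125 for TraesCS2D01G044100, 0.0229 for TraesCS7B01G137200, 0.0353 for TraesCS5A01G143100 and 0.00526 for TraesCS2B01G140300. It was 0.00537 for the WRKY gene TraesCS3A01G116200, 0.0230 for TraesCS2B01G019200 and 0.0296 for TraesCS7D01G201400. The genes named for a line were picked because they differed there from the mean of the other lines. Their low adjusted p in the F test follows largely from that choice and adds no evidence. Among genes named for C20 it was 0.0176 for the MAP65-domain gene on 2D, 9.69e-05 for TraesCS4B01G222300, 0.0173 for TraesCS7A01G420600 and 0.0122 for TraesCS6B01G189800. Among those named for C22 it was 0.0174 for TraesCS7B01G253600, 0.0163 for TraesCS7B01G253700, 0.00242 for TraesCS4A01G256700, 0.0353 for the TPR repeat gene on 6D, 0.0117 for TraesCS1A01G384300 and 0.0261 for TraesCS3B01G283900. Among those named for C40 it was 0.00467 for TraesCS7D01G021100, 0.0332 for TraesCS2D01G409000, 0.0401 for TraesCS5D01G403800 and 0.0201 for TraesCS5A01G533900.

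Transcripts of cell division were high in 7 of the 9 line libraries. Library size or scaling is argued against, since 48 genes of the list had 0 counts in all of WT and averaged at least 100 counts in the lines. A level fixed by the line is argued against by a 7.08-fold range within C20. A larger share of dividing tissue in some samples stays open: over the 7 libraries the level went with a lower Rubisco small subunit share at r = -0.72 (exact permutation p = 0.0760, adjusted 0.0760; rho = -0.71, exact permutation p = 0.0881, adjusted 0.0881; 2 relations; r = -0.63 without C20 replicate 2 and C22 replicate 2). The 7 libraries were picked by their high level, and the share is of raw counts, without TMM scaling. Of the 2 left out, C40 replicate 1 had a WT-like level (1703 CPM) but a share of only 2.28%. C20 replicate 3 had 2109 CPM and 3.63%, nearer to the 3.83% to 4.64% of WT. An effect of the transgene that varies between plants was not tested.

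In C40 the genes of 2A up to 143276770 lay near a log2 difference of -0.91 from WT, or 53.1% of its level. Windows of 20 Mb elsewhere went no lower than -0.37 while those inside reached at most -0.71. Each library's median difference was subtracted first. A scaling error common to all genes is removed by that step, so the windows are no test of it. The segment was also placed by its low level in C40, so part of the gap follows from that choice. Diverged sequence that maps poorly is argued against by a spread between genes only 1.16 times that elsewhere, among 118 genes that moved little in C20 and C22. The loss of 1 of 2 copies is a candidate explanation, as those genes had a median of -0.87 and medians of -0.82, -0.96 and -0.86 in the 3 libraries. It is a hypothesis found on the same data, and DNA was not analysed here.

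Of 13 alternative oxidase genes 7 rose in the mean of the lines, all with close identifiers within 2A, 2B or 2D. A difference in dividing tissue as the whole cause is argued against, since with the cell-division covariate the median rise of the 7 genes was 3.50, against 2.58 without it, and 5 of 7 were still called, while TraesCS2B01G459300 (1.19 ± 0.35 without and 1.43 ± 0.50 with the covariate, SE, adjusted p = 0.130) and TraesCS2D01G436700 (1.07 ± 0.35 and 1.36 ± 0.50, adjusted p = 0.148) were not, since their SE grew in larger proportion than the estimate and fewer genes (3806) passed overall. The 7 genes were picked on the same data, and the estimates of all other members rose with the covariate too, for example TraesCS6A01G269100 from -0.95 to 0.12. WT lay below every line library on the covariate (-1.09 to -0.95, against -0.37 or more), so the adjusted estimates are extrapolated. A defence state of some plants may account for part of the rise in alternative oxidase: over the 9 line libraries alternative oxidase and WRKY levels went together at r = 0.903 (exact permutation p = 5.3e-04, adjusted 0.00106; rho = 0.767, exact permutation p = 0.0214, adjusted 0.0428; 2 relations; r = 0.677 without C20 replicate 2 and C22 replicate 2). These levels were means of log2 CPM over each list, and the permutation leaves out that the 9 libraries came from 3 lines. A defence state is not told apart from tissue make-up here. C20 replicate 2, with the highest cell-division mean of the lines (4.31), had the lowest alternative oxidase and WRKY means (1.92 and 0.636). C20 replicate 3, with the lowest (-0.37), had the highest (4.34 and 2.01). C40 replicate 3 did not follow this, with 3.89, 3.60 and 1.69. The overexpression itself stays open, as it coincides with the lines.

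Other splits of the samples were fitted for the main results. In 100 splits, as many genes changed in the mean of the lines in 1, the real one with 17592 (highest other 8). As many were shared by the lines in 1 (1178, highest other 0). Both shares were under 0.05. Splits that mix WT and line libraries put the difference between them into the spread within groups, so low counts there follow largely by construction. They do not exclude chance, and the labels do not say that the samples are separate plants. As many NAC genes came in 1 (50, highest other 0), which follows the overall count, since 50 of 206 of them changed beside 17592 of 75788 genes, and says nothing of the family. As many lists came in 4 (18, highest other 20), a share under 0.05, but the splits gave 3 to 20 lists, so lists are called for other groupings of these samples too, and with an estimated correlation 0 passed. The count of 0 chromosomes was matched in 100 of 100 because no count is lower, so it says nothing. For single lines 10 splits are too few for a share under 0.05: the real counts were 1862, 13666 and 14103 genes for C20, C22 and C40 and 1 chromosome for C40, each the only 1 of its size, with a highest other of 0.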

How the results depend on the processing

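The covariate and the joint omission of C20 replicate 3 and C40 replicate 1 were chosen after seeing the data. With RLE size factors and with limma on FPKM no count moved by over 1.5 times. Without a filter, with the stricter filter and with the replicate block 1 chromosome passed in the mean of the lines, and with a log2 fold change of at least 1 it was 2, and 2 in C40. The replicate block gave 982 genes in C20, 695 shared and 656 between lines. DESeq2 gave 11861, 20840 and 21535 genes in C20, C22 and C40, 6483 shared, 8480 between lines and 4 chromosomes in C40. With WT alone in the fit C20 had 12 genes and C22 30005. With the estimated correlation 0 lists passed in the mean and in C20, C22 and C40, and with fry 7, 6, 3 and 4. With the covariate 3806 genes changed in the mean, 2926 in C22 and 7484 in C40, 6333 differed between lines, 25 NAC genes changed (25 rose, 0 fell), 3 chromosomes passed in C40, and 11 lists passed in the mean and 7 in C40. The direction of 4 lists was reversed with it, with an adjusted p of 0.455 for cytochrome P450, 0.0120 for the respiratory chain, 0.840 for antioxidant enzymes and 0.0224 for photosystems. These directions are extrapolated, since WT lay below every line library on the covariate. Without the 2 libraries 32263 genes changed in the mean, 19539, 24235 and 26449 in C20, C22 and C40, 11109 were shared, 80 NAC genes changed and 2 chromosomes passed in C40. The cause was not tested for any of these, except that a fold threshold or filter changes the genes counted by construction. Leaving out each library in turn gave 4216 to 26498 genes in the mean, 87 to 12749 in C20, 3388 to 22299 in C22, 4288 to 22910 in C40, 63 to 6739 shared, 293 to 7390 between lines, 16 to 74 NAC genes, 0 to 3 chromosomes in the mean and 1 to 4 in C40, 9.63% to 35.1% of 2A genes in C40, and 14 to 18 lists in the mean, 13 to 17 in C20, 12 to 15 in C22 and 12 to 15 in C40. List membership by protein motif was not run, since transcripts were not used here. In a simulation with 100 changed genes per fold edgeR recovered 8% of 2-fold changes, a rate that does not carry over to comparisons with many more changed genes, where the adjustment is less strict.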

Other observations

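All 1330 Pfam domains with at least 10 tested genes were also tested, which was not among the planned comparisons. By camera 206 were higher and 201 lower in the mean of the lines, and 0 with an estimated correlation, where each domain named here had an adjusted p of 0.824. Among those higher were PCI (61 genes, 8 rose, 0 fell, adjusted p = 6.79e-07), proteasome subunit (59 genes, 5 and 0, 3.72e-06), LSM (39 genes, 16 and 0, 4.06e-06), KH (93 genes, 26 and 5, 5.65e-06) and importin-beta domains (42 genes, 13 and 0, 1.49e-05). Among those lower, of 37 PsbP genes, of the oxygen-evolving part of photosystem II, 21 fell and 0 rose (adjusted p = 6.67e-08). Of 21 DNA photolyase and cryptochrome-type genes 14 fell and 0 rose (adjusted p = 7.49e-07), and of 49 ZIP zinc transporter genes 20 fell and 0 rose (adjusted p = 7.49e-07). Of 62 response regulator genes 19 fell and 0 rose (adjusted p = 2.41e-05), of 53 tify genes, the family of jasmonate repressors, 14 and 0 (adjusted p = 3.79e-05), and of 23 SPX genes, of phosphate sensing, 11 and 0 (adjusted p = 1.86e-05). Of 32 wax ester synthase-type genes 13 fell and 0 rose (adjusted p = 1.15e-05).

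On 2A, the polyketide synthase-type gene TraesCS2A01G021900 starts at 10507367, the hydrolase gene TraesCS2A01G021800 at 10485453 and the P450 gene TraesCS2A01G022800 at 11023897, and all 3 fell in the mean of the lines. They lie in the segment of 2A that had a lower level in C40. TraesCS2A01G022800 fell in C20 (0.340 CPM, adjusted p = 0.00997) and C22 (0.312 CPM, adjusted p = 0.00330) as well, against 7.88 CPM in WT.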
